A study of Mus musculus with 23 samples.

How the data were processed

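Bulk RNA sequencing was done on EpCAM-positive lung epithelial cells of C57BL/6 mice, in 3 experiments (A, B and C) and 4 groups: fresh isolation (3 libraries, 1 per experiment), the day of airlift (6), untreated culture at day 4 (7) and culture with NTHi to the same day (7). Groups and experiments were taken from the labels. The authors deposited 3 tables of raw counts per gene, which are whole numbers and not normalised, with 1 table per experiment and 23 library columns. STAR, DESeq2 and the mouse build GRCm39 are named per the submitters' processing notes, without versions, and the tool that counted reads per gene, its settings and its use of strand are not given in the sources used here. Genes are named by symbol as in the deposited tables. Genes that overlap, or that lie antisense to each other, cannot be told apart without strand. No coordinates are given, because the annotation at hand was of another build.

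Each table held 41098 lines. In each, 25 lines were fragments of longer, broken lines and were left out, which removed 6 genes (Dst, Neb, Ttn, Syne1, Mycbp2 and Huwe1) and 0 to 0.082% of a library's counts. This left 41073 genes. Libraries held between 32323375 and 39081663 counts. Among counts below 20, 69.3% to 74.9% were even, an excess of even values of the kind that counting both reads of a pair gives. If so, the number of independent fragments lies below the count. Replicates of a group within an experiment were compared by a chi-square over genes, and each pair differed by more than sampling noise, so each library was counted once. The floor for a gene with no count covers counting error only.

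Each comparison used edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (minimum count 10), libraries were scaled by TMM, and a quasi-likelihood F-test was fitted with group and experiment as terms, with a Benjamini-Hochberg adjusted p below 0.05 as the threshold. NTHi was compared with control on the 14 day 4 libraries (16337 genes), and the untreated comparisons were made on the 16 libraries of fresh isolation, airlift and day 4 control (18302 genes). The standard error of a log2 fold change was its size divided by the square root of F. CPM were computed on TMM-scaled totals of the 23 libraries. Fresh libraries had TMM factors of 0.741 to 0.77, and the 10 genes with most counts took 23.4% to 23.9% there and 7.7% to 10.0% in other libraries. The 10 mitochondrially encoded genes of the fixed list took 2.99 ± 0.21% of counts in fresh cells (SD, n = 3) and 2.18 ± 0.15% at airlift (SD, n = 6).

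Before the data were examined, 40 gene lists were fixed, and those with at least 3 tested genes were tested with limma 3.58.1 camera, a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 39 lists tested. Camera called 15 lists for NTHi, of which 4 held with an estimated correlation; the numbers were 20 and 5 for airlift against isolation, 20 and 3 for day 4 control against airlift, and 23 and 6 for day 4 control against isolation. The genes named were also set by a rule fixed before: the 5 highest and the 5 lowest log2 fold changes among called genes with an average log2 CPM of at least 2, the same sign in each experiment and a symbol that was not a bare model name; 12 genes whatever their values; and up to 4 members with the smallest p of each list described. Day 4 control against isolation took only the 12 genes. Which of the 40 lists were described, and which of the genes that the rule gives were printed, was chosen after the results were seen. The genes called for a different NTHi effect between experiments, and Pdpn, Adgre1 and Slc34a2 in the NTHi comparison were also named after their values were seen.

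The tests were tried on simulated counts with 200 changed genes, with rises and falls balanced and no other difference between groups. Many more genes were called in the real comparisons, so these runs did not try the scaling under such broad change. For NTHi against control (16337 genes), 73.1% of genes changed by 0.5 on the log2 scale, 97% of those changed by 1 and 100% of those changed by 2 were recovered, and 19 of 15961 unchanged genes were called. For airlift against isolation (18302 genes) the shares recovered were 44.8%, 71.6% and 93.9%. Camera called the 1 changed list and none of 39 others. The simulated genes varied independently of each other, so this run did not try camera on lists whose members move together.

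The alternatives were DESeq2 size factors, DESeq2 1.42.0, no filter on low counts, no experiment term, counts summed per experiment and group, a minimum log2 fold change of 1, leaving out each experiment or each library, a replicate block, a fit on all libraries, and limma-voom with sample weights. Added after the data were examined were scaling by library totals alone, counts divided by 2 and rounded down, the NTHi comparison without 2 libraries that stood apart, and DESeq2's likelihood ratio test of the difference between experiments.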

Results

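RNA was sequenced in bulk from mouse lung epithelial cells that carried the surface marker EpCAM and were grown in transwells at an air-liquid interface, a culture in which the upper face of the cell layer is exposed to air. The 23 libraries came from 3 experiments, named A, B and C, and fell into 4 groups. Freshly isolated cells gave 3 libraries, cells on the day of airlift (the removal of medium from the upper face) gave 6, untreated cultures at day 4 gave 7, and cultures treated with non-typeable Haemophilus influenzae (NTHi), a bacterium of the airways, gave 7. Each experiment held every group. Each library held between 32323375 and 39081663 counts. Nothing in the labels says that the replicates were separate animals or cultures, so the p-values measure the spread between these samples, which may be technical. Levels are normalised counts, in the unit CPM, with their SD, and fold changes are log2 values with their standard error.

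The first comparison asked how NTHi changed the cultures by day 4. Genes of antimicrobial defence and inflammatory signalling rose, and genes of alveolar type 1 (AT1) cells, the flat cells of the gas exchange surface, fell. Lcn2, which encodes an iron-scavenging antibacterial protein, went from 153 ± 46.6 CPM (SD, n = 7) in control cultures to 9051 ± 761 CPM (SD, n = 7) with NTHi, a log2 change of 5.94 ± 0.17. Ager, a marker of AT1 cells, went from 928 ± 97.6 to 297 ± 26.2 CPM (SD, n = 7 each), a log2 change of -1.64 ± 0.07. Foxj1, a regulator of multiciliated cells, was at 145 ± 52.8 CPM in control and 146 ± 48.9 CPM in NTHi cultures, a log2 difference of 0.01 ± 0.08 (adjusted p = 0.95, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

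Of 18 antimicrobial and acute-phase genes measured, 16 rose and 1 fell, both over all genes and adjusted over the list alone. They included Chi3l1 (log2 change 4.49 ± 0.12), the complement component C3 (2.46 ± 0.06) and Duox2, an enzyme that makes hydrogen peroxide at the cell surface, which went from 0.614 ± 0.313 to 53.6 ± 4.85 CPM. Of 24 chemokine and cytokine genes, 20 rose and 2 fell, with the same counts adjusted over the list alone. Cxcl5 and Cxcl1, which attract neutrophils, rose by 5.37 ± 0.11 and 4.82 ± 0.24, Ccl20 by 5.53 ± 0.12, and the growth factors Csf3 and Csf1 by 4.75 ± 0.16 and 2.74 ± 0.09. Of 16 NF-kB feedback genes, 15 rose over all genes and 16 adjusted over the list alone, among them Zc3h12a (3.06 ± 0.05), Nfkbiz (2.67 ± 0.05), Tnfaip3 (1.54 ± 0.05) and Birc3 (1.46 ± 0.04). The camera test called these 3 lists higher, and with an estimated correlation their adjusted p-values were 1.1e-05, 0.0019 and 0.00045, in the order given.

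Smaller rises covered 11 of 12 genes of MHC class I presentation, with Tapbp at 0.58 ± 0.04 and Tap1 at 0.64 ± 0.08, and 12 of 19 interferon response genes, of which 1 fell. Gbp2 rose by 1.92 ± 0.13, Oasl2 by 1.29 ± 0.08 and Irf1 by 0.65 ± 0.04. Adjusted over the list alone, the counts were 11 for MHC class I presentation and 12 higher with 2 lower for the interferon response. Of 16 hypoxia and glycolysis genes 13 rose and 2 fell, also adjusted over the list alone, with Hk2, the hexokinase that starts glycolysis, at 1.04 ± 0.07 and Egln3 at 0.99 ± 0.09. Camera called these 3 lists, but with an estimated correlation the adjusted p was 0.44 for MHC class I presentation, 0.44 for the interferon response and 0.45 for hypoxia and glycolysis.

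Of 15 AT1 genes 14 fell and 1 rose, also adjusted over the list alone, and camera called the list lower, with an adjusted p of 0.011 with an estimated correlation. Aqp5 fell by 1.67 ± 0.06, Emp2 by 1.31 ± 0.04 and Clic5 by 1.11 ± 0.05, while Pdpn rose by 1.59 ± 0.13. The 15 genes of alveolar type 2 (AT2) cells, which make surfactant, were split, with 7 higher and 7 lower, and camera did not call the list, whose median of 0.099 and mean of -0.23 differed in sign. Of these, Sftpc fell by 2.33 ± 0.08, from 2169 ± 277 to 434 ± 52.6 CPM, Sftpb by 3.14 ± 0.12 and Hc by 3.35 ± 0.10. Other AT2 members moved the opposite way. Chi3l1, which is also on the antimicrobial list, rose by 4.49 ± 0.12. The mean level of Slc34a2 was 190.23 CPM in control and 380.84 CPM in NTHi cultures. Of 15 genes of club and secretory cells 10 fell and 2 rose, also adjusted over the list alone, with Scgb1a1 at -0.70 ± 0.07, Scgb3a2 at -4.67 ± 0.19, Cbr2 at -1.11 ± 0.06 and Bpifa1 at -1.43 ± 0.13. Of 14 basal cell genes 9 fell and 2 rose, or 10 and 2 adjusted over the list alone. Krt5 fell by 1.63 ± 0.14, Ngfr by 1.95 ± 0.18, Krt15 by 0.91 ± 0.10 and Trp63 by 0.59 ± 0.14; Trp63 was not called in a fit with no experiment term, at -0.60. Camera called both lists lower, and with an estimated correlation the adjusted p was 0.49 for club and secretory cells and 0.64 for basal cells.

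None of 14 genes of the multiciliated cell programme was called by the edgeR test, and 1 of them, Cep152, had an unadjusted p below 0.05. Of 18 components of motile cilia 5 fell and 1 rose, also adjusted over the list alone, and camera did not call the list. The mucin gene Muc5ac rose by 1.05 ± 0.14 to 7.75 ± 0.991 CPM, while Muc5b differed by 0.27 ± 0.20 and was not called. The ion transport genes Slc26a4 and Cftr rose by 4.39 ± 0.14 and 1.76 ± 0.09. Of 11 airway ion transport genes 6 rose and 4 fell, also adjusted over the list alone, and camera did not call the list. Mki67, a marker of dividing cells, fell by 0.38 ± 0.07. Of 18 proliferation genes 4 fell with none higher, also adjusted over the list alone, and camera did not call the list (adjusted p = 0.30). Besides Mki67, those that fell were Rrm2 (-0.38 ± 0.09), Tyms (-0.23 ± 0.06) and Mcm2 (-0.24 ± 0.08). Rrm2, Tyms and Mcm2 were not called without experiment B, at -0.32, -0.20 and -0.23, nor Tyms and Mcm2 without experiment A, at -0.21 and -0.15. Mcm2 was also not called with a replicate block, at -0.24, or with no experiment term, at -0.22. Krt8, a keratin of simple epithelia, differed by -0.13 ± 0.05 and was not called, but leaving out control replicate 3 of experiment C added the call at -0.16. The largest rises under the naming rule were those of Cstdc4 (8.01 ± 0.39), Sprr2d (7.22 ± 0.31), Csta2 (7.20 ± 0.34), U90926 (6.65 ± 0.36) and Duoxa2 (6.51 ± 0.21). Cstdc4, Csta2 and Sprr2d belong to families of near-identical copies, so their reads may have been divided among copies and the values are uncertain. The largest falls were those of C1qc (-4.67 ± 0.22), Scgb3a2, Cxcr1 (-4.65 ± 0.34), Pld4 (-4.28 ± 0.23) and Rufy4 (-4.26 ± 0.22).

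Markers of immune cells moved with the treatment as well, in both directions. Of 15 macrophage and monocyte genes 11 fell and 1 rose, or 12 and 1 adjusted over the list alone, and camera called the list lower, with an adjusted p of 0.44 with an estimated correlation. C1qa went from 8.41 ± 2.49 to 0.569 ± 0.19 CPM and Ear2 from 70.4 ± 21.6 to 4.57 ± 1.75 CPM, while Adgre1 rose by 1.19 ± 0.23. Of 9 lymphocyte genes 5 fell and none rose, with the B cell genes Ms4a1 at -1.88 ± 0.20 and Cd79a at -0.89 ± 0.15; camera did not call this list. Of 8 neutrophil genes 4 rose and 1 fell, also adjusted over the list alone, and camera did not call the list. Its median was 0.75 and its mean 0.014. As fixed, it shares S100a8, S100a9, Ltf and Camp with the antimicrobial list, so these lists are not separate results.

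**Figure D1:**
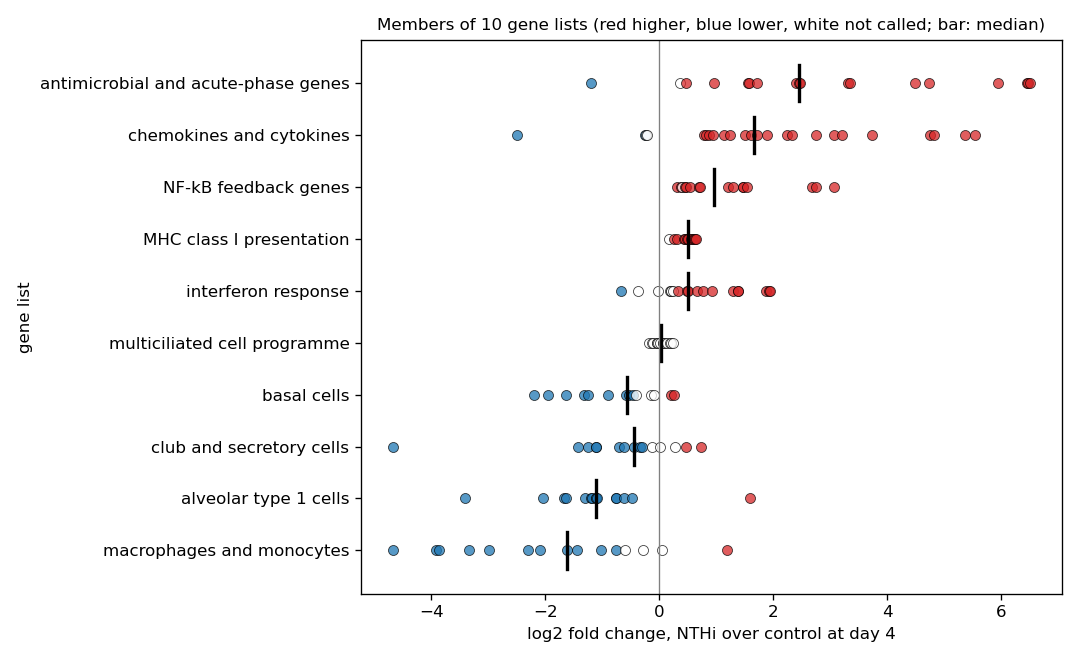
Log2 fold change with NTHi over control at day 4 (x axis) of each measured member of 10 gene lists (y axis), with called genes in red (higher) or blue (lower), others in white, and the list median as a black bar. The antimicrobial list had its median at 2.45 and the AT1 list at -1.11, and no member of the multiciliated programme was called.

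In all, 6619 of 16337 genes were called with the edgeR quasi-likelihood test and Benjamini-Hochberg adjustment, 3281 higher and 3338 lower with NTHi, and 98.6% of them had the same sign in the 3 experiments, a share that the choice of genes on the same libraries raises. Tested separately, experiment A called 3389 genes, experiment B 3067 and experiment C 2617, and 1625 were called with the same sign in each. No gene was called for a different NTHi effect between experiments by edgeR, and DESeq2 called 5 (Pigr, Reg3g, Acaa1b, Abhd17a and Romo1). In the edgeR test 675 of 16337 genes had an unadjusted p below 0.05, a share under the 1 in 20 that chance alone would give. When libraries were scaled by their totals alone, 2282 genes were higher and 4416 lower. With 2 experiment C libraries that stood apart left out, 6816 genes were called.

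The next comparison set cells at airlift against freshly isolated cells. The lists of AT2 cells, of club and secretory cells and of MHC class II presentation fell, while most proliferation genes and most hypoxia and glycolysis genes rose. Camera called these last lists higher, but their adjusted p was 0.16 and 0.13 with an estimated correlation. Sftpc went from 63120 ± 10150 CPM (SD, n = 3) in fresh cells to 576 ± 61.2 CPM (SD, n = 6) at airlift, a log2 change of -6.75 ± 0.12. Mki67 went from 24.2 ± 2.98 to 71.2 ± 8.89 CPM, a log2 change of 1.57 ± 0.10. In fresh cells 1 gene, Scgb1a1, the secretoglobin of club cells, took 11.05% to 12.29% of the counts of a library, and it fell by 2.77 ± 0.12 at airlift.

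Of 15 AT2 genes 14 fell and 1 rose, with Slc34a2 at -6.86 ± 0.11, Etv5 at -3.89 ± 0.07 and Lpcat1 at -3.67 ± 0.07. All 15 genes of club and secretory cells fell, including Cyp2f2 (-6.39 ± 0.18), Chad (-5.34 ± 0.13) and Scgb3a2 (-8.15 ± 0.24). The 7 genes of MHC class II presentation fell, with H2-Eb1 at -4.58 ± 0.07, H2-Aa at -4.18 ± 0.07 and Cd74 at -3.21 ± 0.06. The 13 genes that mark tissue dissociation and the immediate-early response also fell, such as Fosb (2854 ± 319 to 10.5 ± 2.66 CPM), Fos (-4.86 ± 0.12) and Nr4a1 (-5.05 ± 0.14). These counts did not differ when adjusted over the list alone. Camera called these 4 lists lower, and with an estimated correlation the adjusted p-values were 0.00027, 0.033, 0.00085 and 0.041 in the same order. All 18 components of motile cilia fell, with Tppp3 at -2.44 ± 0.10 and Dnai1 at -2.21 ± 0.12, and Foxj1 fell by 1.31 ± 0.14, but with an estimated correlation the adjusted p of the list was 0.27. Among secreted products, Muc5b fell by 5.52 ± 0.23, Muc5ac by 3.69 ± 0.21, Lcn2 by 3.08 ± 0.17 and Cxcl1 by 4.24 ± 0.26. Of 15 AT1 genes 7 rose and 7 fell, or 8 and 7 adjusted over the list alone and 9 and 5 with scaling by library totals, and camera did not call the list, whose median of 0.24 and mean of -0.38 differed in sign. The AT1 marker Ager was among those that fell, by 1.29 ± 0.12, and the basal keratin Krt5 fell by 1.75 ± 0.45, while Trp63 differed by -0.67 ± 0.40 and was not called. Some markers of other cell types were lower as well, in 8 of 12 lymphocyte, 6 of 9 neutrophil and 10 of 12 endothelial genes, with none higher and the same counts adjusted over the list alone. Camera called these lists lower, and with an estimated correlation the adjusted p-values were 0.39, 0.31 and 0.42. Of 15 macrophage and monocyte genes 11 fell and 1 rose, and of 11 mesenchymal genes 4 rose and 3 fell, also adjusted over the list alone, and camera called neither list.

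Of 16 hypoxia and glycolysis genes 13 rose and none fell, or 14 adjusted over the list alone, with Eno1 at 4.22 ± 0.09, Pgk1 at 3.26 ± 0.09 and Ldha at 2.83 ± 0.09. Of 18 proliferation genes 17 rose and 1 fell, also adjusted over the list alone, including Ccnb1 (3.09 ± 0.11), Cdk1 (2.70 ± 0.12) and Top2a (2.41 ± 0.12). Of 19 interferon response genes 16 rose and 1 fell, also adjusted over the list alone, with Oasl2 at 3.20 ± 0.16 and Gbp2 at 2.09 ± 0.13. Camera called the 3 lists higher, and the adjusted p-values with an estimated correlation were 0.13, 0.16 and 0.31. The largest rises under the naming rule were those of Ndufa4l2, Tmt1b (8.88 ± 0.32), Nrk (8.61 ± 0.24), Adam12 (7.54 ± 0.25) and Itga2 (7.51 ± 0.15). Ndufa4l2 had no count in the fresh libraries, and its 11.4 ± 2.05 CPM at airlift was at least 328-fold higher than the floor of 3 counts over that group, taking each count as 1 fragment; the bound is lower if both reads of a pair were counted. The largest falls were those of Prmt8 (-9.96 ± 0.31), Clca1 (-8.80 ± 0.25), Scgb3a2, Fosb (-8.09 ± 0.18) and Kcnh4 (-8.04 ± 0.44). At airlift Prmt8, Clca1 and Kcnh4 were at 0.036 ± 0.064, 0.17 ± 0.074 and 0.11 ± 0.10 CPM (SD, n = 6). In fresh cells Tmt1b, Nrk and Adam12 were at 0.047 ± 0.041, 0.095 ± 0.040 and 0.12 ± 0.039 CPM (SD, n = 3). At such low levels the sizes of these changes are uncertain.

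The edgeR test called 13646 of 18302 genes, 6928 higher and 6718 lower at airlift, and 98.5% of these, chosen on the same libraries, had the same sign in the 3 experiments. Scaled by library totals alone, 10131 genes were higher and 4223 lower, with the median of all genes at 0.49, so the changes above are relative to the bulk of genes; under that scaling Krt8, at -0.21 ± 0.07 above, was 0.28 higher. Leaving out the experiment B library of fresh cells ended the call of Krt8 (-0.17), as did leaving out all libraries of experiment A (-0.19) or B (-0.14), and leaving out that of experiment A added a call for Trp63 at -1.08.

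Day 4 control cultures were then set against cells at airlift, the 2 untreated stages of the culture. Most genes of AT2 cells, basal cells and the multiciliated programme rose, and most genes of hypoxia and glycolysis, the interferon response and proliferation fell. With an estimated correlation camera kept the calls of AT2 cells and of hypoxia and glycolysis, while the adjusted p was 0.34 for basal cells, 0.34 for the multiciliated programme, 0.093 for the interferon response and 0.30 for proliferation. Krt5 went from 9.9 ± 6.27 CPM (SD, n = 6) to 103 ± 46.1 CPM (SD, n = 7), a log2 change of 3.24 ± 0.39. Foxj1 went from 59.4 ± 24.2 to 145 ± 52.8 CPM, a log2 change of 1.21 ± 0.11. Pgk1, a glycolytic enzyme, went from 1962 ± 76.6 to 399 ± 39 CPM, a log2 change of -2.31 ± 0.06.

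Of 15 AT2 genes 13 rose and none fell, also adjusted over the list alone, with Egfl6 at 4.55 ± 0.14, Slc34a2 at 3.96 ± 0.09, Lpcat1 at 2.07 ± 0.06 and Sftpc at 1.92 ± 0.09. Of 15 AT1 genes 8 rose and 2 fell, also adjusted over the list alone, with Rtkn2 at 3.78 ± 0.24, Pdpn at 2.01 ± 0.10 and Ager at 1.31 ± 0.10. Of 14 basal cell genes 12 rose and none fell, or 13 adjusted over the list alone, among them Ngfr (3.93 ± 0.28), Krt14 (3.75 ± 0.38), Col17a1 (3.74 ± 0.27) and Trp63 (2.71 ± 0.30). Of 14 genes of the multiciliated programme 9 rose and 1 fell, also adjusted over the list alone, with Mcidas at 5.56 ± 0.40, Ccno at 4.12 ± 0.24 and Deup1 at 3.39 ± 0.27. Camera called these 4 lists higher, and the adjusted p with an estimated correlation was 0.0054 for AT2 cells, 0.34 for AT1 cells, 0.34 for basal cells and 0.34 for the multiciliated programme. Muc5b rose by 2.61 ± 0.20 and Muc5ac by 2.04 ± 0.19, while Scgb1a1 fell further, by 2.91 ± 0.10. Of 15 club and secretory genes 6 rose and 7 fell, or 6 and 8 adjusted over the list alone. Camera did not call that list, whose median log2 change of -0.23 and mean of 0.39 differed in sign. Lcn2 rose by 1.45 ± 0.15, and Cxcl1 differed by 0.56 ± 0.24 (adjusted p = 0.053, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Cxcl1 was called when 1 library was left out, at 0.66 and 0.64 without airlift replicates 1 and 2 of experiment A, 0.62 and 0.69 without control replicates 1 and 2 of experiment A, 0.65 without control replicate 2 of experiment B and 0.63 without control replicate 1 of experiment C.

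Of 11 genes that mark mesenchymal cells 10 rose and none fell, also adjusted over the list alone, and camera called the list higher, with an adjusted p of 0.0054 with an estimated correlation. The collagen genes Col1a2 and Col3a1 rose by 3.21 ± 0.17 and 2.47 ± 0.13, to 67.1 ± 33.9 and 36.3 ± 16.5 CPM, and Acta2 by 2.09 ± 0.14 to 26.7 ± 10.1 CPM. Of 15 macrophage and monocyte genes 9 rose and 4 fell, also adjusted over the list alone, and camera did not call the list.

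Of 16 hypoxia and glycolysis genes 15 fell and none rose, also adjusted over the list alone, with Car9 at -3.19 ± 0.09 and Pfkp at -2.12 ± 0.07. Of 19 interferon response genes 18 fell, also adjusted over the list alone, with Oas2 at -2.21 ± 0.12 and Irf7 at -2.18 ± 0.10. Of 18 proliferation genes 17 fell, also adjusted over the list alone, with Cenpf at -1.04 ± 0.10, Ccna2 at -0.85 ± 0.07, Birc5 at -0.84 ± 0.08 and Mki67 at -0.37 ± 0.07. Camera called the 3 lists lower, with adjusted p-values of 0.021, 0.093 and 0.30 with an estimated correlation. Krt8 fell by 0.68 ± 0.06. The largest rises under the naming rule were those of Cym (6.51 ± 0.25), Rgs5 (6.40 ± 0.30), Mcidas, Rgs4 (5.55 ± 0.23) and Ivl (4.65 ± 0.16), and the largest falls those of Tmt1b (-5.91 ± 0.16), Stab2 (-4.99 ± 0.28), Muc2 (-4.46 ± 0.12), Ndufa4l2 (-4.39 ± 0.14) and Edn2 (-3.69 ± 0.51).

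The edgeR test called 9982 of 18302 genes, 4919 higher and 5063 lower at day 4, and 95.7% of these, chosen on the same libraries, had the same sign in the 3 experiments.

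**Figure D2:**
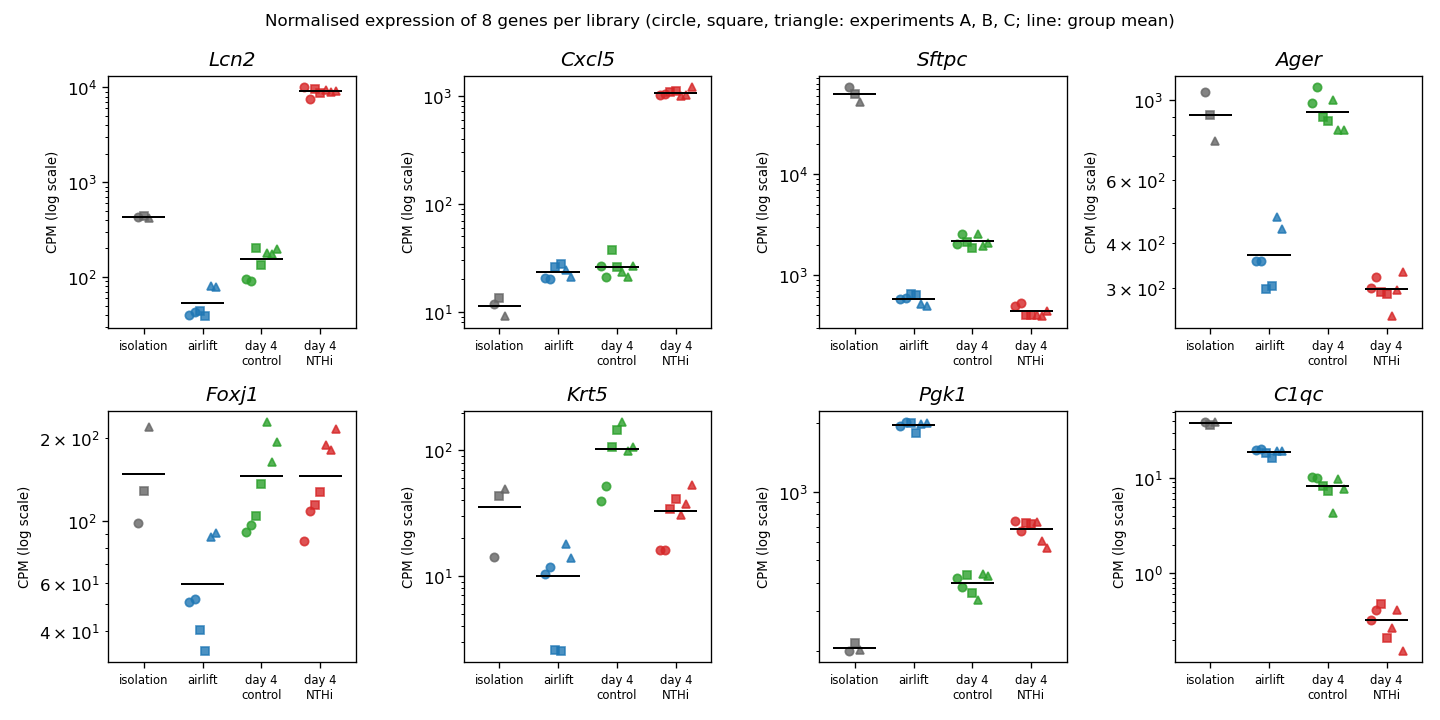
Normalised level (y axis, CPM on a log scale) of 8 genes in each of the 23 libraries by group (x axis), with circles, squares and triangles for experiments A, B and C and a line at the group mean. Lcn2 had a mean of 9051 CPM with NTHi and 153 CPM in control cultures, and Sftpc fell from 63120 CPM in fresh cells to 576 CPM at airlift.

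Against freshly isolated cells, day 4 control cultures still had lower AT2, club cell and MHC class II genes. Of 15 AT2 genes 14 were lower and 1 higher, of 15 club and secretory genes 14 were lower, and the 7 MHC class II genes were lower, with the same counts adjusted over the list alone; camera called the 3 lists, with adjusted p-values of 0.0035, 0.029 and 0.0015 with an estimated correlation. Sftpc was lower by a log2 change of -4.84 ± 0.11 and Scgb1a1 by -5.68 ± 0.12. The 13 dissociation and immediate-early genes were also lower, as were 11 of 14 sterol and fatty acid synthesis genes, with 1 higher. Of 14 EGF and FGF signalling genes 10 were lower and 4 higher. Camera called these lists lower too, and with an estimated correlation the adjusted p-values were 0.037, 0.019 and 0.041. Krt5, Trp63 and Mki67 were higher by 1.49 ± 0.45, 2.03 ± 0.38 and 1.2 ± 0.09, and Muc5b, Muc5ac, Lcn2, Cxcl1 and Krt8 were lower by -2.91 ± 0.20, -1.65 ± 0.18, -1.62 ± 0.17, -3.68 ± 0.24 and -0.89 ± 0.07. Ager differed by 0.02 ± 0.12 and Foxj1 by -0.11 ± 0.14, and neither was called, but with libraries scaled by their totals alone both were called higher, at 0.50 and 0.37. Markers of other cell types differed too: 10 of 12 lymphocyte and 10 of 12 endothelial genes were lower with none higher, 7 of 9 neutrophil genes were lower and 2 higher, and 7 of 11 mesenchymal genes were higher and 2 lower, with the same counts adjusted over the list alone. Camera called these 4 lists, and with an estimated correlation the adjusted p-values were 0.36, 0.44, 0.16 and 0.16. The edgeR test called 14012 of 18302 genes, 7108 higher and 6904 lower at day 4, with the same sign in the 3 experiments for 98.7% of these, chosen on the same libraries. Scaled by library totals alone, 10149 were higher and 4497 lower, with the median of all genes at 0.49.

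The last comparison asked how NTHi acted on the genes that changed between airlift and day 4. The genes were chosen in 2 experiments and their NTHi effect was read in the experiment left out, so that no control library served both. Called genes that rose to day 4 by a log2 change of at least 1 had a median log2 difference between NTHi and control of -0.21 in experiment A, -0.24 in B and -0.18 in C, and 61.1%, 61.3% and 58.8% of them were lower with NTHi. With no minimum change the medians were closer to 0, at -0.066, -0.044 and -0.044. Genes that fell to day 4 by at least 1 had medians of 0.081, 0.057 and -0.014, and with no minimum 0.037, 0.027 and 0.011. No test was made across the 3 experiments; a two-sided exact sign test could not go below p = 0.25 there.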

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

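The tests of the macrophage list's members were chosen after their values were seen; the tests on splits, on the most abundant genes and on the libraries that stood apart were set before their results were seen. The splits within each experiment for the 3 untreated comparisons, and the shift of the median gene without the most abundant genes, were added after the other splits and the number of calls had been seen.

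Values of the genes chosen for the text and of library totals were examined in 348 groups of 6 or 7 libraries for a library far from the others, and 25 were found, where chance sets apart about 1 in 20 groups, or 17.4. The 348 groups cover only genes chosen for the text, a selection made after a wider screen had been seen; over the 334 genes that the naming rule gives, 68 of 1002 groups held such a library. At airlift, experiment C replicate 1 was highest for Ccno (2.82 CPM), Cym (2.17 CPM), Mcidas (0.816 CPM), Rgs4 (2.47 CPM) and Rtkn2 (2.32 CPM). Experiment C replicate 2 was lowest for Etv5 (19.0 CPM), and experiment A replicate 2 was highest for C1qa (19.0 CPM). Experiment B replicate 2 at airlift was highest for Clca1 (0.316 CPM) and Prmt8 (0.158 CPM) and had the lowest share of its 10 top genes (7.7%). Among control cultures, experiment B replicate 1 was highest for Csta2 (0.996 CPM), Cstdc4 (0.548 CPM), Cxcl5 (37.4 CPM) and Irf7 (29.9 CPM). Experiment C replicate 1 was highest for Acta2 (47.6 CPM), Adam12 (53.4 CPM) and Rtkn2 (34.2 CPM) and lowest for Pfkp (53.8 CPM). Among NTHi cultures, experiment C replicate 3 was highest for Birc5 (13.99 CPM), Ccna2 (20 CPM), Cdk1 (36.1 CPM), Muc5ac (9.81 CPM), Rrm2 (20.3 CPM) and Rtkn2 (2.91 CPM), and experiment A replicate 2 for Birc3 (159 CPM). Of experiment C, control replicate 1 and NTHi replicate 3 lay at -37.4 and -41.0 on the second principal component of the day 4 libraries (14.8% of variance), with the others between -14.9 and 32.2.

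Of 15 macrophage and monocyte genes 11 fell with NTHi, 1 rose and the others were not called. Camera called the list lower, but with an estimated correlation its adjusted p was 0.44. The 2 experiment C libraries that stood apart are not the source: without both, the median log2 change of the 15 genes was -1.57. A loss of macrophages that all carry the same markers would lower the abundant markers alike. Adgre1 rose by 1.19 ± 0.23 and Ear2 fell by 3.93 ± 0.26, a difference of 5.11 ± 0.35. They are the highest and the lowest of 12 abundant members, picked after their values were seen. Their gap therefore does not settle whether the number of macrophages changed. A change of expression within macrophages, with or without a change in their number, stays open as a hypothesis that these bulk libraries did not test. The cells had been selected for EpCAM, which would remove most macrophages, so the source of these transcripts is open too.

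Splits of the libraries asked whether chance in how they fell into groups could give as many called genes in the 4 comparisons. They treat single libraries as exchangeable, which would not hold if replicates within an experiment were technical. A split that mixes the groups also carries their difference into the spread, which lowers its calls. The splits therefore show only whether another examined split gave as many genes, and they do not exclude chance. Over splits that ignored the experiment, 60 were examined of 1716, 84, 1716 and 120 possible ones for NTHi, airlift against isolation, day 4 control against airlift and day 4 control against isolation. In each case 1 split, the real one, gave as many genes. The real splits called 6619, 13646, 9982 and 14012 genes and the highest others 0, 0, 8321 and 0. Over splits within each experiment, 60 of 360 were examined for NTHi, all 27 for airlift against isolation, 60 of 360 for day 4 control against airlift and all 36 for day 4 control against isolation. Again 1 split, the real one, gave as many, and the highest others gave 1849, 0, 8321 and 0. In the split with 1849, a side held 6 of the 7 NTHi libraries, so that split is close to the real one. The split with 8321 shared 1 of the 7 control libraries with the real group and so is close to its mirror. In experiment C alone the 10 splits are too few for a share below 0.05; the real one called 2617 genes and the highest other 0.

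A few genes took a large share of the counts in fresh cells. Without the 10 genes with most counts there, 13781 genes were called for airlift against isolation, but TMM already trims such genes and the median gene moved by only 0.0062 on the log2 scale. The bound set before, a number of calls within 1.5 times of the reported one, was therefore met by a removal that decides nothing, and the part played by these genes stays open.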

How the results depend on the processing

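Scaling by library totals, counts divided by 2, leaving out 2 experiment C libraries together, DESeq2's likelihood ratio test, and the settings for separate experiments were chosen after the data were examined. Leaving out each library in turn gave 6069 to 6702 called genes for NTHi, 12799 to 13579 for airlift against isolation, 9393 to 9968 for day 4 control against airlift and 13247 to 14024 for day 4 control against isolation. Other settings, apart from a minimum fold, gave 4925 to 6988, 12355 to 14458, 7750 to 10125 and 12791 to 15182. A minimum log2 fold change of 1 left 1235, 6521, 2465 and 6822 genes, by its own construction. With counts divided by 2, 14957 genes passed the filter in place of 16337, so fewer could be tested at lower counts, and 6390 were called for NTHi.

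Deviations of same-numbered NTHi and control libraries had correlations across genes of 0.093 in experiment A, 0.13 in B, and -0.50, 0.14 and -0.31 in C. In C each was below the highest value for a library of another number (0.55, 0.35 and 0.29), so replicate numbers showed no pairing there. A and B, with 2 libraries per group, give 1 value each, which cannot settle whether the numbers pair the libraries. With the replicate number as a block there were 5982 calls for NTHi and 8768 for day 4 control against airlift, and the block ended the call of Mcm2 for NTHi, with its change at -0.24 in both fits. With no experiment term Trp63 (-0.60) and Mcm2 (-0.22) were not called for NTHi.

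For a different NTHi effect between experiments, 5 genes were called with no filter (Acaa1b, Lcn2, Pigr, Reg3g and Rsad2) and 5 with DESeq2's likelihood ratio test (Pigr, Reg3g, Acaa1b, Abhd17a and Romo1), against 0 by edgeR as reported and 0 without each library in turn; the cause was not tested. With an estimated correlation 4, 5, 3 and 6 gene lists were called in the order above, and fry, which does not compare a list with other genes, called 27 for NTHi and 34 for airlift against isolation. Genes that rose to day 4 had a median NTHi difference of -0.044 with no minimum fold, where genes of smaller change enter.

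Of 3952 values of the genes chosen for the text under alternatives, 3884 kept direction and side of the threshold, 31 lost the call (20 through the minimum fold), 20 gained it and 17 changed sign, of which 1 was of a called gene. That was Krt8 in airlift against isolation, at 0.28 with scaling by library totals. Among genes not called, Ager in day 4 control against isolation was at -0.027 with DESeq2 size factors, -0.027 with DESeq2, -0.025 with counts divided by 2, -0.033 without experiment C, and -0.13 to 0.11 without each library. With scaling by totals Foxj1 was at 0.37 there and Ager at 0.50, and both were called. For NTHi, Foxj1 was at -0.052 with that scaling, -0.0017 without experiment A and -0.037 to 0.050 without each library, and Muc5b at -0.038 without experiment A; the cause was not tested.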

Other observations

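The gene families and the cytokine in this part were chosen after the data were examined, and no test was made over a family as a whole. With NTHi, the 8 measured carboxylesterase genes of the Ces1 and Ces2 families, enzymes that split ester bonds in lipids and drugs, were lower, from Ces2g at -0.94 to Ces2c at -6.12 ± 0.38. Of 23 glutathione transferase genes 13 were lower and 2 higher, and of 31 cytochrome P450 genes 13 were lower and 4 higher. Of 10 small proline-rich genes, which encode parts of the cornified envelope, 8 were higher and 1, Sprr1a, lower at -1.09. The list of squamous and hillock genes, fixed before the data were examined, includes some small proline-rich genes and was split. Of its 16 measured genes 5 were higher and 5 lower, or 6 and 6 adjusted over the list alone, and camera did not call it. Of the other families looked at, Ly6 genes had 4 of 15 higher and 2 lower, and tetraspanins 8 of 19 higher and 5 lower. The 3 measured genes of the stefin cluster, which encode inhibitors of cysteine proteases, were higher by 6.15 to 8.01. Members of these families are similar in sequence, so the values of single members are uncertain.

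Of 7 genes of the interleukin 1 family, 6 were higher with NTHi and Il18 fell by 2.50 ± 0.17, from 20.4 ± 4.63 to 3.64 ± 0.763 CPM (SD, n = 7 each). Il1b went from 64.2 ± 14.5 to 318 ± 119 CPM. Il22, which encodes a cytokine of lymphoid cells, was at 0.0353 ± 0.0544 CPM in control and 2.01 ± 1.01 CPM in NTHi cultures, while 73 of 105 immunoglobulin genes were lower and 1 was higher. Of 23 genes picked by symbols like those of complement genes, 12 were higher and 6 lower, from C1s1 at 3.13 to C1qc at -4.67. The pick took any symbol that begins with C1q, C1r or C1s. It can therefore hold genes that are not complement components and miss components named otherwise.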
